A study of Mus musculus with 19 samples.

How the data were processed

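Bone marrow was flushed with cold PBS from the tibiae and femurs of mice and frozen, RNA was extracted with Trizol, and polyadenylated RNA was made into libraries with the Kapa mRNA Hyper kit and read in pairs on a NovaSeq X, per the labels. The submitters' processing notes list Salmon 1.4.0, DESeq2 with no version and the mm10 genome, without saying what each did or in which order. The deposited values are normalized counts, a signal in which the authors divided the gene counts of each library by a size factor. In every library 100% of the values were whole multiples of a single step, within a tolerance of 0.001 read, so whole reads were recovered by dividing by that step. Size factors computed with DESeq2 from these reads matched the deposited scaling, with ratios from 0.998 to 1.01. The annotation release and any filter of the authors are not stated. No pair of libraries within a genotype was a duplicate (lowest chi-square per degree of freedom 15.5).

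The table holds 34432 genes, of which 11764 have no reads in any library and 34415 were matched by Ensembl ID to GENCODE vM21, the source of the GRCm38/mm10 coordinates. Libraries held 14881701 to 33010241 reads assigned to genes. A count of 0 has an upper 95% limit of 3 reads, which is 0.0909 to 0.202 per M reads at these depths; this floor covers counting error only and not the spread between libraries. The 13976 genes with a mean of at least 10 normalized counts over all 19 libraries were tested, of which 13972 were matched to the annotation. Symbols shared by more than 1 gene (52 genes) were kept apart by ID. All samples of the table were used.

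Groups, comparisons, tests, gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined. Values were taken as log2(normalized count + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend), with all 5 groups in the fit and no covariate. The comparisons were CDK8KO against VAV, CDK19KO against WT, DKO against VAV, VAV against WT, DKO against CDK8KO, DKO against CDK19KO, and the interaction, DKO minus CDK8KO less CDK19KO minus WT. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene passed at an adjusted p under 0.05. Targeted genes were also tested by exact permutation, whose smallest two-sided p is 0.0286 for 4 against 4 and for 3 against 4 libraries.

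Gene lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 30 lists of at least 5 tested genes; camera with a correlation estimated from the data and fry stood beside it. The preset correlation lets lists of co-regulated genes pass easily. The lists, with the number of genes tested, were Mediator kinase module (7), Mediator core (26), stem and progenitor cells (19), early granulocyte (12), late neutrophil (23), monocyte and macrophage (24), dendritic cell (14), eosinophil, basophil and mast cell (18), erythroid (29), heme synthesis (13), megakaryocyte and platelet (23), B cell precursor (18), mature B cell (24), plasma cell (15), T cell (23), NK cell (18), stroma, bone and vessel (28), skeletal muscle (16), interferon-stimulated genes (34), immediate early genes (25), NF-kappaB and inflammatory genes (22), Wnt and beta-catenin targets (14), Notch targets (8), cholesterol and lipid synthesis (27), glycolysis and HIF targets (25), p53 targets (24), integrated stress and unfolded protein response (26), S phase (30), mitosis (30), cell adhesion and marrow retention (16). The sex-linked list had 4 tested genes and no test. Within a list, a second adjustment over its members alone is given beside the call over all genes.

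The rule named up to 12 genes per direction for CDK8KO against VAV, CDK19KO against WT and DKO against VAV, and up to 5 for the other comparisons. These were the genes with the largest log2 fold change among those that passed, with a mean of at least 50 in a compared group and no overlap between the libraries of the groups (a condition not used for the interaction). Predicted genes, V, D and J segments and sex-linked genes were left out of the rule. Of the genes the rule named for DKO against VAV, 1 is not reported here. Also named were the kinase module and up to 4 members with the smallest p of each list that camera called. Other genes in the text were chosen after their values were seen and were not carried through the alternatives. The set of genes that changed in DKO against VAV, CDK8KO and CDK19KO was also defined after the data were seen. Values after ± are the SD for normalized counts and the SE for log2 fold changes. Among the genes outside the rule for DKO against VAV were Prss34, Siglecf, Gata2, Hdc, Aen, Prdm1, Ighg1, Ncr1, Bcl2a1b, Cd209a and Slc7a11.

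The method was tested on simulated data with the depth and spread of these libraries, in which 100 genes were changed by 1 and 100 by 2 on the log2 scale in DKO against VAV. It recovered 76% and 100% of them, with 12 false calls among 188 (6.38%) and 0 calls in an unchanged comparison. The interaction recovered 44% and 89%, and a list that was moved ranked 1. The alternative settings fixed then were pseudocounts of 0.5 and 8, no filter and a filter at a mean of 50, TMM scaling, quantile normalization, only the compared groups in the fit, array weights, the replicate number as a block, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, other controls, and each library left out in turn. Chosen after the data were seen were the fits without the 2 muscle-rich libraries (CDK19KO replicate 4 and DKO replicate 4), without the 2 erythroid-rich libraries (CDK8KO replicate 1 and VAV replicate 3) and with the mean log2 level of the erythroid list as a covariate.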

Results

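Polyadenylated RNA was sequenced from bone marrow flushed from the tibiae and femurs of 8-week-old C57BL/6 mice of 5 genotypes. CDK8 and CDK19 are paralogous kinases, either of which can occupy the kinase module of Mediator, the complex that links transcription factors to RNA polymerase II. The groups were wild type (WT, n = 3), mice with only the Vav-iCre transgene, which expresses Cre recombinase in blood cells (VAV, n = 4), floxed Cdk8 with Vav-iCre (CDK8KO, n = 4), Cdk19 null (CDK19KO, n = 4) and the combination of both (DKO, n = 4). Reads assigned to genes numbered 16376215 to 25580469 in WT, 25472258 to 33010241 in VAV, 20574294 to 29206413 in CDK8KO, 17649591 to 24598256 in CDK19KO and 14881701 to 26492553 in DKO. The labels number the libraries within a genotype but do not say that each came from a separate animal, so p-values measure the spread between these libraries, which may be partly technical. Y-linked genes were expressed in all 19 libraries, with Ddx3y between 1468 and 2422 normalized counts. The other 3 sex-linked genes tested, Eif2s3y, Kdm5d and Uty, were also present in every library.

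Red cell and muscle transcripts differed between libraries within a genotype. Erythroid genes (29 markers of red cell precursors, hemoglobin included) took 0.162 to 4.09% of reads, and the highest shares were those of CDK8KO replicate 1 (4.09%) and VAV replicate 3 (3.55%). Skeletal muscle genes took 0.609% of reads in CDK19KO replicate 4 and 0.135% in DKO replicate 4, against at most 0.00792% in the other libraries.

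**Figure D1:**
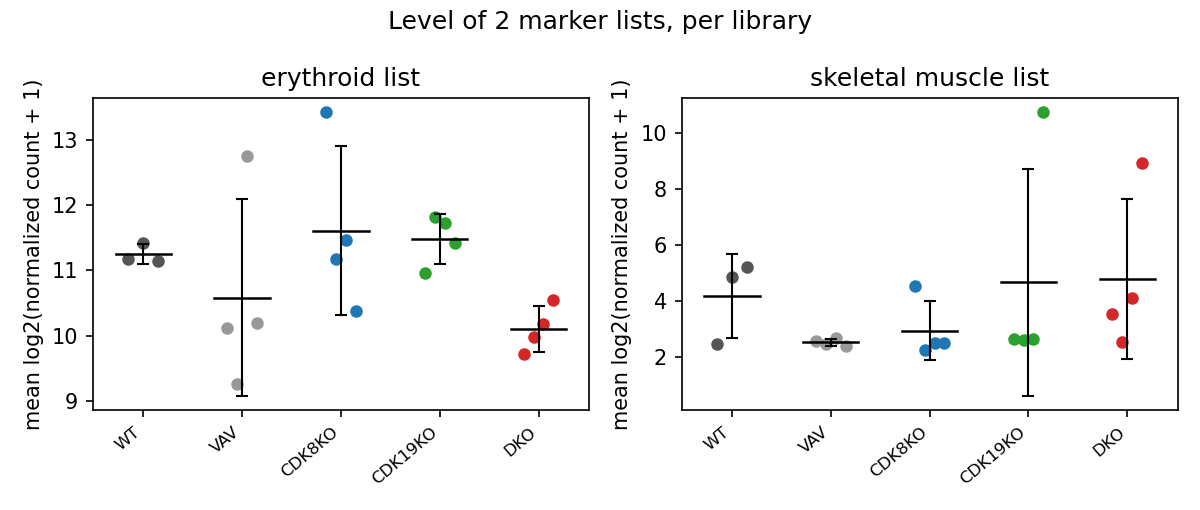
Mean log2(normalized count + 1) of the erythroid and the skeletal muscle lists in each library (points), by genotype, with the group mean (line) and SD (bar). In the muscle panel CDK19KO replicate 4 sits at 10.7, above the 2.61 to 2.64 of the other CDK19KO libraries.

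Cdk19 (ENSMUSG00000038481; GRCm38/mm10 chromosome 10, 40339564 to 40483818) fell in both genotypes that lack it. Its level was 3157 ± 99.7 normalized counts in WT (SD, n = 3) and 1091 ± 62.5 in CDK19KO (SD, n = 4), or 34.5% of WT, a log2 fold change of -1.53 ± 0.12 (SE; limma adjusted p = 9.8e-07). It was 3668 ± 525 in VAV, 3200.5 ± 411 in CDK8KO and 1173 ± 43.1 in DKO (SD, n = 4 each), and the DKO level was 32.0% of VAV (log2 fold change -1.63 ± 0.11, limma adjusted p = 5.5e-08). Every library of the 2 Cdk19-null genotypes, between 1025 and 1202, lay below every other library, the lowest of which held 2710 (exact permutation test, two-sided p = 0.0286 for CDK19KO against WT and for DKO against VAV, the smallest these group sizes allow).

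Cdk8 (ENSMUSG00000029635; chromosome 5, 146231230 to 146302874) was not reduced in the libraries labelled CDK8KO. Its level was 994 ± 230.1 in VAV and 1013 ± 249 in CDK8KO (SD, n = 4 each), a log2 fold change of 0.02 ± 0.17 (SE; exact permutation test, two-sided p = 0.886). It was 1241 ± 34.5 in WT (SD, n = 3), 1132 ± 149 in CDK19KO and 798 ± 62.0 in DKO (SD, n = 4 each). DKO held 80.3% of the VAV level (exact permutation test, two-sided p = 0.143) and 70.4% of the CDK19KO level (exact two-sided p = 0.0286, but limma adjusted p = 0.151). A count over the whole gene does not check the removal of an exon, since a shortened transcript still gives reads, so the Cdk8 genotype rests on the labels here. The difference between CDK8KO and VAV turned negative without VAV replicate 2 (log2 fold change -0.08), VAV replicate 4 (-0.03), CDK8KO replicate 1 (-0.11) or CDK8KO replicate 2 (-0.01), and was -0.33 against WT.

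Commd10 (ENSMUSG00000042705; chromosome 18, 46958816 to 47234284), the gene in which a widely used Vav-iCre transgene is inserted, separated the genotypes labelled with Cre from the others. It stood at 429 ± 66.4 in WT (SD, n = 3) and 341 ± 21.4 in CDK19KO, and at 1275 ± 157 in VAV, 1546 ± 479.9 in CDK8KO and 1494 ± 271 in DKO (SD, n = 4 each). The labels do not name the transgene's line. Of the kinase module's other members, Ccnc, Med12, Med12l, Med13 and Med13l, none passed the test in any comparison; the largest change in DKO against VAV was -0.33 on the log2 scale for Med12l (SE 0.37, limma adjusted p = 0.708).

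**Figure D2:**
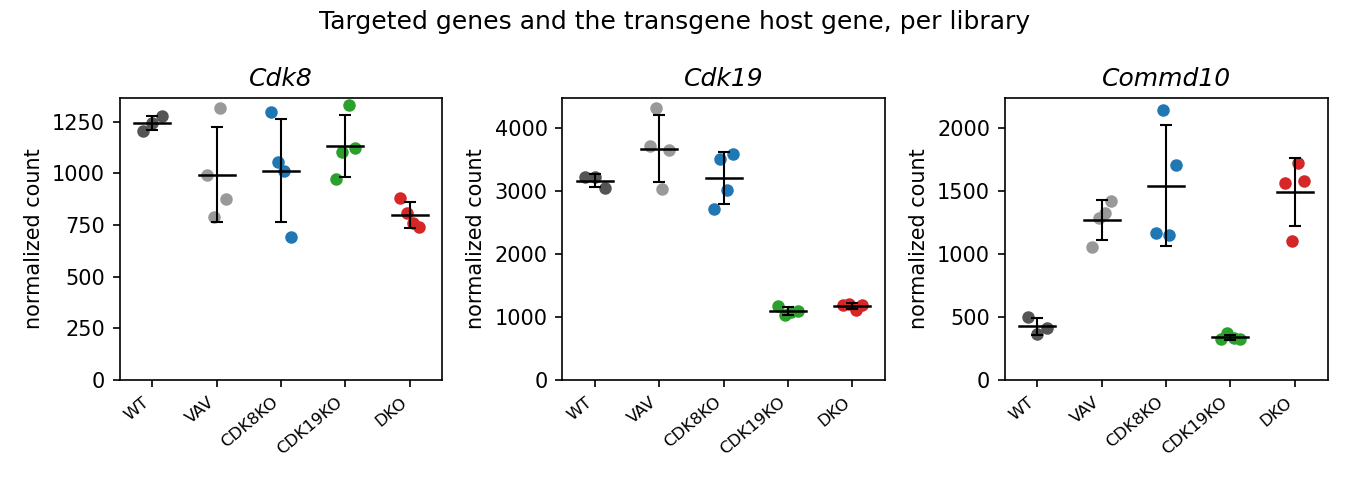
Normalized counts of Cdk8, Cdk19 and Commd10 in each library (points), by genotype, with the group mean (line) and SD (bar). Cdk19 lies between 1025 and 1202 in CDK19KO and DKO, Cdk8 overlaps between VAV and CDK8KO, and Commd10 lies at 1055 or above in the libraries with Cre.

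The comparison of CDK8KO with VAV asks what deletion of Cdk8 in blood cells changes. No gene passed the test. All 29 erythroid markers were higher in CDK8KO, with a median log2 fold change of 1.11, and none passed (camera adjusted p = 1.9e-09, and adjusted p = 0.641 with an estimated correlation). This median was 0.59 without VAV replicate 2 and 0.48 without CDK8KO replicate 1. Among them were the transferrin receptor Tfrc (10427 ± 9103 in VAV, 22971 ± 18947 in CDK8KO; SD, n = 4 each) and Hemgn (log2 fold change 1.12 ± 0.55). All 13 heme synthesis genes were higher as well (median 0.78; camera adjusted p = 6.7e-05, and adjusted p = 0.641 with an estimated correlation). Their median was 0.48 without VAV replicate 2, 1.25 without VAV replicate 3 and 0.24 without CDK8KO replicate 1, and -0.0535 with the erythroid level as a covariate. The erythroid share of reads was 4.09% in CDK8KO replicate 1 and 3.55% in VAV replicate 3, against at most 1.10% in the other libraries of these genotypes. Interferon-stimulated genes were lower for 31 of 34 members, such as Ifit3 (234 ± 85.2 in VAV, 144 ± 55.8 in CDK8KO) and Oas3 (log2 fold change -0.53 ± 0.21). None passed (camera adjusted p = 3.0e-07, and adjusted p = 0.641 with an estimated correlation). All 12 early granulocyte genes were lower, with a median of -0.43 (camera adjusted p = 6.7e-05, and adjusted p = 0.641 with an estimated correlation), which was -0.23 without VAV replicate 4 and -0.25 without CDK8KO replicate 1. Of the megakaryocyte and platelet genes 22 of 23 were lower, with Gp1ba at 1350.1 ± 930.5 in VAV and 545 ± 519 in CDK8KO (camera adjusted p = 9.8e-05, and adjusted p = 0.728 with an estimated correlation). Leaving out 1 library lost the camera call (adjusted p in brackets) for heme synthesis genes without CDK8KO replicate 1 (up to 0.193) and megakaryocyte and platelet genes without VAV replicate 3 (up to 0.291).

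Of the other lists that camera called for CDK8KO against VAV, S phase genes (26 of 30 higher, median 0.16) and mature B cell genes (22 of 24 higher, median 0.24) were higher. Stromal, bone and vessel genes (22 of 28 lower), glycolysis and HIF targets (22 of 25), stress and unfolded protein response genes (22 of 26), the eosinophil, basophil and mast cell list (14 of 18) and adhesion genes (11 of 16) were lower. No call on these 7 lists held with an estimated correlation, where their adjusted p was 0.791, 0.889, 0.643, 0.641, 0.641, 0.728 and 0.641 in that order. The limma-trend count of 0 stood beside 1161 genes at an unadjusted p under 0.05, where 698.8 would be expected by chance, and beside 0 genes in edgeR and 1 in DESeq2. The smallest limma adjusted p was 0.586. The count was 1 without VAV replicate 3, 12 with WT as the control, 4 with WT and VAV pooled and 1 with only these 2 groups in the fit. The S phase median was 0.31 without VAV replicate 3, -0.03 without CDK8KO replicate 1, 0.28 without CDK8KO replicate 2 and 0.26 without CDK8KO replicate 3. The mature B cell median was 0.01 without VAV replicate 1, 0.46 without VAV replicate 3, 0.53 without CDK8KO replicate 2 and -0.13 without CDK8KO replicate 3. With 1 library left out the camera call was lost (adjusted p in brackets) for S phase genes without CDK8KO replicate 1 (up to 0.854), mature B cell genes without VAV replicates 1 or 4 or CDK8KO replicates 3 or 4 (up to 0.585), stromal, bone and vessel genes without VAV replicate 3 or CDK8KO replicates 3 or 4 (up to 0.31), glycolysis and HIF target genes without VAV replicate 4 or CDK8KO replicate 1 (up to 0.0736), stress response genes without VAV replicate 4 or CDK8KO replicates 1, 2 or 3 (up to 0.172), eosinophil, basophil and mast cell genes without VAV replicates 2 or 4 or CDK8KO replicates 1 or 3 (up to 0.514) and adhesion genes without VAV replicates 2 or 4 or CDK8KO replicates 1 or 3 (up to 0.193).

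The comparison of CDK19KO with WT asks what loss of Cdk19 alone changes. Besides Cdk19 itself, 2 genes fell. Il4ra (ENSMUSG00000030748; chromosome 7, 125552120 to 125579474), a receptor chain for interleukin-4 and interleukin-13, went from 2224 ± 313 in WT (SD, n = 3) to 1048 ± 206 in CDK19KO (SD, n = 4), 2.14-fold lower (log2 fold change -1.09 ± 0.17, limma adjusted p = 0.0237). Ttyh1 (ENSMUSG00000030428; chromosome 7, 4119408 to 4136708), a membrane protein, went from 59.3 ± 23.7 to 4.63 ± 3.95 (log2 fold change -3.60 ± 0.60, limma adjusted p = 0.0425). Ttyh1 was also low in genotypes that keep Cdk19, at 6.94 ± 1.78 in VAV and 3.14 ± 0.625 in CDK8KO. No gene rose by limma with these settings, while genes rose in others (5 with DESeq2, 4 with VAV as the control, 2 with array weights, 2 with only these 2 groups in the fit, 1 with the controls pooled and 1 without a filter). T cell genes were lower for 19 of 23 members, with Trac at 153 ± 92.2 in WT and 70.2 ± 16.5 in CDK19KO, and none passed (camera adjusted p = 0.0127, and adjusted p = 0.842 with an estimated correlation). Interferon-stimulated genes were higher for 30 of 34 members (median 0.14; camera adjusted p = 4.0e-04, and adjusted p = 0.842 with an estimated correlation), and this median was 0.01 without CDK19KO replicate 1. Leaving out 1 library lost the camera call (adjusted p in brackets) for T cell genes without WT replicates 1 or 3 (up to 0.666) and interferon-stimulated genes without WT replicate 1 or CDK19KO replicate 1 (up to 0.299).

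The other 8 lists called by camera for CDK19KO against WT had a camera adjusted p = 0.0453 and, with an estimated correlation, adjusted p = 0.842. They were the eosinophil, basophil and mast cell (15 of 18 higher), B cell precursor (16 of 18 higher), plasma cell (11 of 15 higher), cholesterol and lipid synthesis (18 of 27 higher) and stress response lists (18 of 26 higher), and the mature B cell (20 of 24 lower), immediate early (19 of 25 lower) and kinase module lists. The kinase module call went with Cdk19, its only member past the test, while 4 of its 7 members were higher. At an unadjusted p under 0.05 stood 429 genes, with 698.8 expected by chance. The count of 3 was 1 without WT replicate 1, 1 without WT replicate 3, 1 without CDK19KO replicate 2 and 1 without CDK19KO replicate 4. It was 15 with DESeq2, 12 with VAV as the control, 7 with array weights, 6 without a filter on low values and 1 without the 2 libraries rich in muscle transcripts. Il4ra was not called without WT replicates 1 or 3 or CDK19KO replicates 2, 3 or 4 (adjusted p up to 0.247). Ttyh1 was not called without WT replicates 1, 2 or 3 or CDK19KO replicates 1, 2 or 4 (adjusted p up to 0.346). With 1 library left out the camera call was lost (adjusted p in brackets) for eosinophil, basophil and mast cell genes without WT replicates 2 or 3 or CDK19KO replicates 1, 3 or 4 (up to 0.285), B cell precursor genes without WT replicates 1 or 2 or CDK19KO replicate 1 (up to 0.299), plasma cell genes without WT replicates 2 or 3 or CDK19KO replicates 1, 3 or 4 (up to 0.144), cholesterol and lipid synthesis genes without WT replicates 2 or 3 or CDK19KO replicates 1 or 2 (up to 0.324), stress response genes without WT replicates 2 or 3 or CDK19KO replicates 2 or 4 (up to 0.332), mature B cell genes without WT replicates 1 or 3 or CDK19KO replicates 1, 2 or 3 (up to 0.327), immediate early genes without WT replicates 1, 2 or 3 or CDK19KO replicates 2 or 3 (up to 0.267) and kinase module genes without WT replicates 1, 2 or 3 or CDK19KO replicates 1 or 4 (up to 0.144).

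The comparison of DKO with VAV asks what the loss of both kinases changes, and here 213 genes passed, 116 higher and 97 lower, 138 of them by over 2-fold; which direction held more genes depended on the setting, as given below. The gene with the smallest adjusted p apart from Cdk19 was Asprv1 (ENSMUSG00000033508; chromosome 6, 86628164 to 86629710), which encodes an aspartic protease and went from 965 ± 265 normalized counts in VAV to 28.4 ± 9.36 in DKO (SD, n = 4 each), 33.1-fold lower (log2 fold change -5.05 ± 0.34, limma adjusted p = 5.5e-08). Cd163 (ENSMUSG00000008845; chromosome 6, 124304656 to 124330527), the macrophage scavenger receptor for hemoglobin bound to haptoglobin, fell 8.08-fold, from 550.4 ± 117 to 67.0 ± 12.2 (log2 fold change -3.01 ± 0.21, limma adjusted p = 6.5e-08). Perp (ENSMUSG00000019851; chromosome 10, 18845020 to 18857073), a p53 target that encodes a membrane protein, rose 16.2-fold, from 27.7 ± 7.70 to 455 ± 48.0 (log2 fold change 4.02 ± 0.32, limma adjusted p = 5.2e-07). Chit1 (ENSMUSG00000026450; chromosome 1, 134111242 to 134151540), a chitinase of macrophages, rose 6.07-fold to 525 ± 154. Fcnb (ENSMUSG00000026835; chromosome 2, 28076378 to 28084885), a lectin of immature myeloid cells, fell 7.61-fold from 5765 ± 1857 to 760.3 ± 230.3, and H1f0 (ENSMUSG00000096210; chromosome 15, 79028450 to 79030504), a linker histone, 5.56-fold from 884 ± 213 to 157 ± 28.4. Fold changes are on the scale of log2(normalized count + 1), which understates the change of low genes.

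Among the genes named by the rule for the largest changes, 12 rose. Adamdec1, a metalloprotease-like gene, went from 2.28 ± 2.38 to 99.3 ± 105 (SD, n = 4 each). Upp1, a uridine phosphorylase, went from 77.7 ± 20.5 to 496 ± 72.2, and Aspa from 18.3 ± 10.03 to 133 ± 90.5. Adamtsl1, Muc20 and Plekha6 rose by 3.60, 2.53 and 2.50 on the log2 scale. The eosinophil genes Ear6, Prg3, Prg2 and Epx are given with their list. Of the 12 that fell, Thbs1, the thrombospondin of platelets and macrophages, went from 9032 ± 4019.5 to 1621 ± 476. Nt5e, the ectonucleotidase CD73, went from 479 ± 177 to 113 ± 44.6, and Cxcr1, a chemokine receptor, from 57.7 ± 22.7 to 4.19 ± 2.43. Pdzk1 fell by 3.60 on the log2 scale and the immunoglobulin constant gene Ighg2c by 3.41. The natural killer cell receptor Klra4, whose reads may be shared with near-identical Klra genes, fell by 2.36. The heat shock gene Hspa1b fell by 2.33, but VAV replicate 1 held 356 normalized counts and the other VAV libraries 56.2 to 68.5. Over the 24 genes the limma adjusted p ran from 5.5e-08 to 0.0283. With each library left out in turn 18 of them kept the call. Adamtsl1 was not called without VAV replicates 1 or 2 or DKO replicates 1, 2 or 4 (adjusted p up to 0.0787). Plekha6 was not called without VAV replicates 1, 2 or 4 or DKO replicates 1 or 4 (adjusted p up to 0.067). Epx was not called without VAV replicate 1 or DKO replicates 3 or 4 (adjusted p up to 0.0695). Prg2 was not called without VAV replicate 1 or DKO replicates 3 or 4 (adjusted p up to 0.0759). Ighg2c was not called without DKO replicates 3 or 4 (adjusted p up to 0.0566). Hspa1b was not called without VAV replicate 1 or DKO replicates 1, 2, 3 or 4 (adjusted p up to 0.0752).

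**Figure D3:**
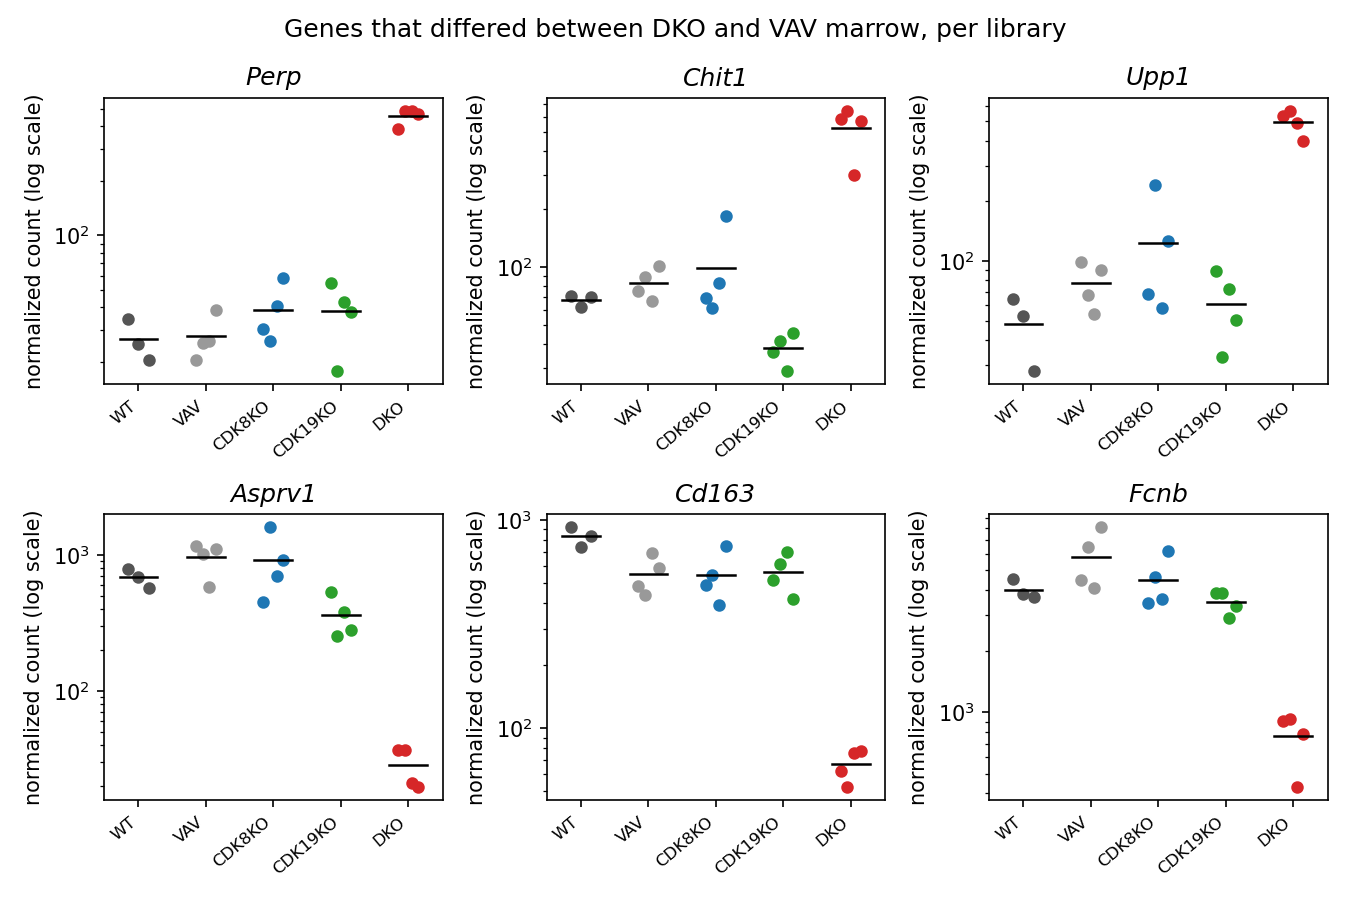
Normalized counts of 6 genes in each library (points) on a log axis, by genotype, with the group mean (line). In DKO, Perp, Chit1 and Upp1 average 455, 525 and 496, and Asprv1, Cd163 and Fcnb average 28.4, 67.0 and 760.3.

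Genes of eosinophils, basophils and mast cells rose: 8 of 18 tested passed, none fell and 10 did not pass, and 14 rose when adjusted over the list alone (camera adjusted p = 3.0e-15, and adjusted p = 0.109 with an estimated correlation). The granule protein genes Ear6 (53.8 ± 30.3 in VAV, 796 ± 784 in DKO; SD, n = 4 each), Prg3 (32.7 ± 8.44 and 292 ± 232), Prg2, the major basic protein (479.6 ± 249.7 and 3365 ± 3328) and Epx, the eosinophil peroxidase (373 ± 309.8 and 1906 ± 995), rose most. Fcer1a, the IgE receptor of basophils and mast cells (log2 fold change 1.51 ± 0.21), the basophil proteases Mcpt8 (1.19 ± 0.23) and Prss34 (0.98; limma adjusted p = 0.0458) and the eosinophil receptor Siglecf (1.09; limma adjusted p = 0.0491) also passed. Gata2 (log2 fold change 0.09, limma adjusted p = 0.858) and Hdc (-0.13, limma adjusted p = 0.793), which is widely expressed in the myeloid lineage, did not. The Ear genes are a family of near-identical copies, so the value of each is uncertain. Mcpt8 was not called without DKO replicate 4 (adjusted p up to 0.0519). The mean log2 level of the list was highest in DKO replicates 3 and 4 (10.23 and 9.80). It was 9.06 and 9.03 in DKO replicates 1 and 2, and 7.88 to 8.63 in VAV.

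**Figure D4:**
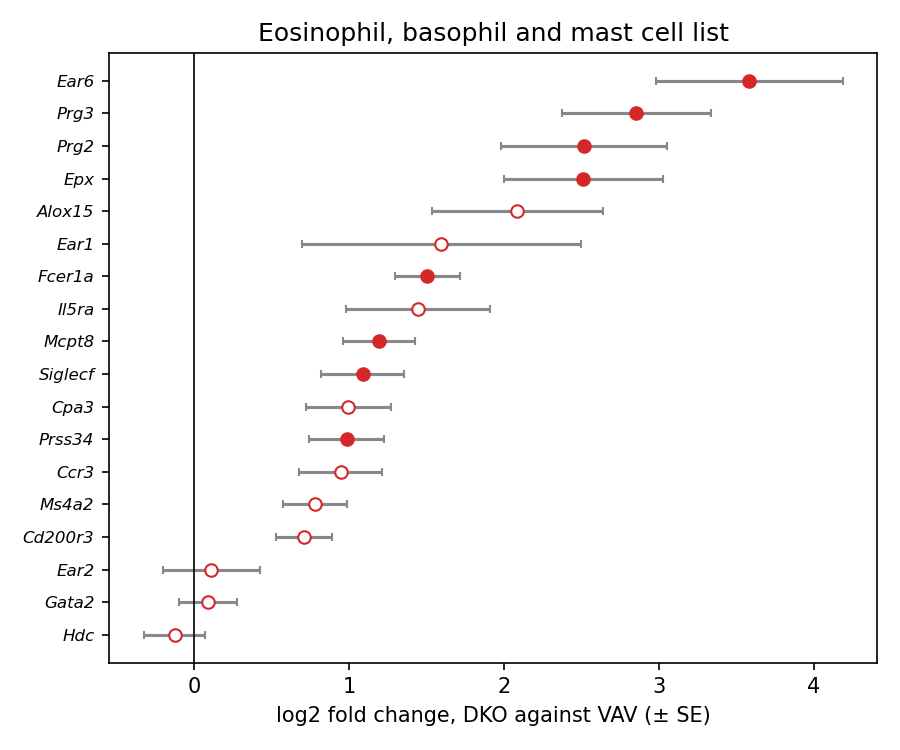
Log2 fold change of DKO against VAV (points, with SE as bars) for the 18 tested genes of the eosinophil, basophil and mast cell list. Filled points passed the test at a limma adjusted p under 0.05 (8 genes); Hdc alone lies below 0, at -0.13.

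Of 24 monocyte and macrophage genes 3 fell and 21 did not pass (4 fell adjusted over the list alone; camera adjusted p = 0.00145, and adjusted p = 0.555 with an estimated correlation). Beside Cd163 these were Cd5l, a secreted macrophage scavenger protein (131 ± 25.5 in VAV, 49.3 ± 13.1 in DKO), and the heme oxygenase Hmox1 (4673 ± 1036 and 2312 ± 505). Of 23 late neutrophil genes 3 fell, Mmp8 (log2 fold change -1.04 ± 0.20), Camp (-0.82 ± 0.16) and Il1b (-1.55 ± 0.38), and 9 fell adjusted over the list alone (camera adjusted p = 3.9e-05, and adjusted p = 0.585 with an estimated correlation). The mean log2 level of the late neutrophil list in DKO (13.50 to 13.90) overlapped that in WT (13.53 to 13.75) and CDK19KO (13.31 to 13.76). It was 13.72 to 14.14 in VAV, where most of these genes were higher than in WT, as given below. Of 25 immediate early genes 3 fell, Fos (1753 ± 1164 and 441 ± 130.5), Dusp1 (4643 ± 1678 and 2028 ± 343) and Egr1 (209 ± 48.1 and 78.2 ± 29.8). Of this list 6 fell adjusted over the list alone (camera adjusted p = 4.6e-04, and adjusted p = 0.555 with an estimated correlation). All 23 megakaryocyte and platelet genes were lower, with a median of -1.07; Thbs1 alone passed and 9 fell adjusted over the list alone (camera adjusted p = 3.9e-09, and adjusted p = 0.555 with an estimated correlation). The median of this list was -1.71 without VAV replicate 2 and -0.59 without VAV replicate 3. All 23 T cell genes were higher, with a median of 0.77; Cd8a passed (119 ± 24.9 and 449.9 ± 165), and 6 rose adjusted over the list alone (camera adjusted p = 5.8e-09, and adjusted p = 0.555 with an estimated correlation). The mean log2 level of the T cell list was 7.83 to 8.12 in DKO replicates 2, 3 and 4, but 6.69 in DKO replicate 1, within the 6.63 to 7.12 of VAV. Of 27 cholesterol and lipid synthesis genes Insig1 (log2 fold change 0.70 ± 0.15) and Cyp51 (0.78 ± 0.17) rose, and 6 rose adjusted over the list alone (camera adjusted p = 0.00232, and adjusted p = 0.593 with an estimated correlation). Hmox1 was not called without DKO replicates 1 or 4 (adjusted p up to 0.0556). Il1b was not called without VAV replicates 1, 3 or 4 or DKO replicates 2, 3 or 4 (adjusted p up to 0.176). Egr1 was not called without VAV replicates 1 or 2 or DKO replicates 1 or 2 (adjusted p up to 0.0653). Insig1 was not called without VAV replicates 2 or 3 or DKO replicate 2 (adjusted p up to 0.0711). Cyp51 was not called without VAV replicates 1, 2 or 3 or DKO replicates 2 or 4 (adjusted p up to 0.062). Leaving out 1 library lost the camera call (adjusted p in brackets) for cholesterol and lipid synthesis genes without VAV replicate 3 or DKO replicate 2 (up to 0.0613).

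In 5 further lists that camera called for DKO against VAV no member passed. Interferon-stimulated genes were higher for 29 of 34 (median 0.33; camera adjusted p = 8.6e-06, and adjusted p = 0.585 with an estimated correlation). S phase genes were lower for 29 of 30 (median -0.29; camera adjusted p = 8.6e-06, and adjusted p = 0.593 with an estimated correlation), and mitosis genes for 27 of 30 (median -0.26; camera adjusted p = 8.6e-06, and adjusted p = 0.593 with an estimated correlation), among them Mki67 (log2 fold change -0.72 ± 0.22). The S phase median was -0.17 without VAV replicate 3. Most mitosis genes were higher in VAV than in WT, as given below. Erythroid genes were lower for 28 of 29 (median -0.52; camera adjusted p = 0.0121, and adjusted p = 0.82 with an estimated correlation), and this median was -0.93 without VAV replicate 2 and 0.26 without VAV replicate 3, the VAV library with the largest erythroid share. Muscle genes were higher for all 16 tested (camera adjusted p = 0.0024, and adjusted p = 0.634 with an estimated correlation), with 0.135% of reads in DKO replicate 4 against at most 0.00398% in the other DKO and in the VAV libraries. Leaving out 1 library lost the camera call (adjusted p in brackets) for erythroid genes without VAV replicate 3 or DKO replicate 1 (up to 0.329) and skeletal muscle genes without DKO replicate 4 (up to 0.37). The kinase module list was called through Cdk19 (camera adjusted p = 0.00361, and adjusted p = 0.126 with an estimated correlation). By fry, a test that rotates the residuals, only the eosinophil, basophil and mast cell list (adjusted p = 0.00168) and the kinase module list (adjusted p = 5.1e-04) were called for DKO against VAV.

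The remaining 17 lists were not called for DKO against VAV. In p53 targets Perp and Aen (log2 fold change 0.80) rose and 22 of 24 did not pass (median 0.01). In the plasma cell list Prdm1 (0.91) and Ighg1 (2.41) rose and Ighg2c fell (median of 15 genes 0.24). In the NK cell list Klra4 and Ncr1 (-1.28) fell (median of 18 genes 0.20). In the NF-kappaB list Bcl2a1b rose (1.94) and Il1b fell (median of 22 genes 0.05). In the dendritic cell list Cd209a fell (-1.50; median -0.16). In the stress response list Slc7a11 fell (-0.84; median 0.01), and in the early granulocyte list Fcnb (median -0.16). No member passed in the lists for the Mediator core (median -0.09), stem and progenitor cells (-0.26), heme synthesis (-0.34), B cell precursors (0.06), mature B cells (-0.10), stroma, bone and vessel (-0.13), Wnt targets (0.08), Notch targets (0.19), glycolysis and HIF targets (-0.10) and adhesion (-0.21).

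The count of 213 for DKO against VAV was 125 without VAV replicate 1, 136 without VAV replicate 2, 107 without DKO replicate 3 and 116 without DKO replicate 4. It was 504 with DESeq2, 99 with only these 2 groups in the fit, 366 with WT and VAV pooled as the control, 102 without the 2 muscle-rich libraries, 385 without the 2 erythroid-rich libraries and 606 with the erythroid level as a covariate. With WT as the control it was 293, of which 91 were among the 213. Lower genes outnumbered higher ones in several settings. The higher and lower genes numbered 223 and 383 with the covariate, 160 and 225 without the erythroid-rich libraries, 50 and 52 without the muscle-rich libraries, and 110 and 114 with array weights. They numbered 103 and 123 without VAV replicate 3, 81 and 83 without DKO replicate 2, and 56 and 60 without DKO replicate 4.

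DKO was also compared with each single knockout. Against CDK8KO, 238 genes passed, 147 higher and 91 lower. Eosinophil, basophil and mast cell genes rose in 12 of 18 cases (16 adjusted over the list alone), led by Ear6 (log2 fold change 4.54 ± 0.60) and Epx (3.70 ± 0.51), and this was the only list call of the study that held with an estimated correlation (camera adjusted p = 2.0e-20, and adjusted p = 0.0363 with an estimated correlation). The mean log2 level of this list was 9.03 to 10.23 in DKO and 7.48 to 8.19 in CDK8KO, against 7.88 to 8.63 in VAV and 8.35 to 8.57 in WT. Adamdec1 (4.47 ± 0.83), Perp (3.58 ± 0.32) and Prg3 (3.37 ± 0.48) rose too. Asprv1 (-4.87 ± 0.34), Ighg2c (-3.11 ± 0.67), Klra4 (-3.07 ± 0.38), Cd163 (-2.98 ± 0.21) and Fcnb (-2.57 ± 0.24) fell, all with limma adjusted p up to 0.0224. Interferon-stimulated genes rose in 7 of 34 cases, 18 adjusted over the list alone, among them Iigp1 (139 ± 21.2 in CDK8KO, 347 ± 66.0 in DKO) and Irf7 (420.2 ± 103 and 758 ± 59.2) (camera adjusted p = 7.9e-17, and adjusted p = 0.205 with an estimated correlation). All 30 S phase genes were lower with none past the test, 17 adjusted over the list alone (camera adjusted p = 1.1e-13, and adjusted p = 0.464 with an estimated correlation). All 29 erythroid genes were lower, of which Car1 fell (-1.52 ± 0.32), 15 adjusted over the list alone (camera adjusted p = 1.0e-13, and adjusted p = 0.466 with an estimated correlation). The erythroid share of reads was 0.508 to 4.09% in CDK8KO and 0.211 to 0.501% in DKO.

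Camera called 13 further lists for DKO against CDK8KO, none of which held with an estimated correlation. Mediator kinase module genes (0 of 7 rose and Cdk19 fell) had adjusted p = 0.202 with an estimated correlation. Mediator core genes (21 of 26 lower) had adjusted p = 0.276 with an estimated correlation. Late neutrophil genes (2 of 23 fell) had adjusted p = 0.699 with an estimated correlation. Monocyte and macrophage genes (3 of 24 fell) had adjusted p = 0.548 with an estimated correlation. Heme synthesis genes (all 13 lower) had adjusted p = 0.536 with an estimated correlation. Megakaryocyte and platelet genes (Thbs1 of 23 fell) had adjusted p = 0.699 with an estimated correlation. Mature B cell genes (22 of 24 lower) had adjusted p = 0.724 with an estimated correlation. Plasma cell genes (2 of 15 rose and 1 fell) had adjusted p = 0.548 with an estimated correlation. T cell genes (Cd8a of 23 rose) had adjusted p = 0.536 with an estimated correlation. Skeletal muscle genes (15 of 16 higher) had adjusted p = 0.699 with an estimated correlation. Immediate early genes (Egr1 of 25 fell) had adjusted p = 0.699 with an estimated correlation. Cholesterol and lipid synthesis genes (22 of 27 higher) had adjusted p = 0.466 with an estimated correlation. Mitosis genes (29 of 30 lower) had adjusted p = 0.548 with an estimated correlation. The count of 238 was 123 without CDK8KO replicate 1, 422 without CDK8KO replicate 4, 119 without DKO replicate 2, 139 without DKO replicate 3 and 105 without DKO replicate 4. It was 711 with DESeq2 (328 higher and 383 lower, the opposite majority), 106 with array weights, 31 with only these 2 groups in the fit and 92 without the 2 muscle-rich libraries. With the erythroid level as a covariate the megakaryocyte and platelet median turned from -0.48 to 0.40 (camera adjusted p = 0.0128), and the heme synthesis median from -1.16 to 0.05. With no covariate these medians were -0.14 without CDK8KO replicate 1 and -0.59 without CDK8KO replicate 1, in that order. The T cell level of DKO replicate 1 (6.69) lay within that of CDK8KO (6.52 to 7.72). Ighg2c was not called without CDK8KO replicate 3 or DKO replicates 3 or 4 (adjusted p up to 0.081). Irf7 was not called without DKO replicates 2 or 4 (adjusted p up to 0.0576). Car1 was not called without CDK8KO replicate 1 or DKO replicates 3 or 4 (adjusted p up to 0.0692). Cd8a was not called without CDK8KO replicate 1 or DKO replicates 2, 3 or 4 (adjusted p up to 0.0612). Egr1 was not called without DKO replicate 2 (adjusted p up to 0.0501). Leaving out 1 library lost the camera call (adjusted p in brackets) for Mediator core genes without DKO replicate 4 (up to 0.067), late neutrophil genes without CDK8KO replicates 2 or 4 or DKO replicate 3 (up to 0.356), monocyte and macrophage genes without CDK8KO replicate 4 or DKO replicate 1 (up to 0.192), megakaryocyte and platelet genes without CDK8KO replicate 1 (up to 0.475), mature B cell genes without CDK8KO replicates 3 or 4 or DKO replicates 1 or 2 (up to 0.972), plasma cell genes without CDK8KO replicates 1 or 2 or DKO replicates 1, 3 or 4 (up to 0.217), skeletal muscle genes without CDK8KO replicates 2, 3 or 4 or DKO replicate 4 (up to 0.7) and immediate early genes without CDK8KO replicates 3 or 4 or DKO replicates 1 or 2 (up to 0.688).

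Against CDK19KO, 279 genes passed in DKO, 187 higher and 92 lower; this pair differs in Cre as well as in Cdk8. Prox1 (-4.73 ± 0.32) fell and Commd10 (2.11 ± 0.18) rose, the direction of both in VAV against WT. Interferon-stimulated genes rose in 9 of 34 cases, 22 adjusted over the list alone, with Ifit1 at 201 ± 77.6 in CDK19KO and 526 ± 126 in DKO (camera adjusted p = 3.6e-15, and adjusted p = 0.264 with an estimated correlation). Cholesterol and lipid synthesis genes rose in 7 of 27 cases, 15 adjusted over the list alone, among them Msmo1 (0.96 ± 0.16) and Insig1 (0.90 ± 0.15) (camera adjusted p = 1.4e-11, and adjusted p = 0.264 with an estimated correlation). Both of these lists were also higher in VAV against WT (33 of 34 and 24 of 27 members), so Cdk8 deletion cannot be told apart from Cre or colony for them. Of the eosinophil, basophil and mast cell list 5 of 18 rose, 10 adjusted over the list alone (camera adjusted p = 1.7e-08, and adjusted p = 0.264 with an estimated correlation). Fcer1a, Mcpt8, Cpa3 and Prss34 were among the 5. The mean log2 level of this list was 10.23 and 9.80 in DKO replicates 3 and 4. It was 9.06 and 9.03 in DKO replicates 1 and 2, near the top of the CDK19KO range (8.27 to 9.05). Of monocyte and macrophage genes 6 of 24 fell and 1 rose, with Cd163 (-3.04 ± 0.21), Cd5l (-2.44 ± 0.25) and the mannose receptor Mrc1 (-1.23 ± 0.18) among the former (camera adjusted p = 3.7e-04, and adjusted p = 0.528 with an estimated correlation). T cell genes were higher for all 23, and Cd28 (1.21 ± 0.23) and Cd8a (1.67 ± 0.34) rose, 11 adjusted over the list alone (camera adjusted p = 8.6e-09, and adjusted p = 0.528 with an estimated correlation). The list was higher in DKO replicates 2, 3 and 4 only: its mean log2 level was 6.69 in DKO replicate 1 and 6.73 to 7.03 in CDK19KO. Chit1 (3.70 ± 0.30), Perp (3.63 ± 0.32), Adgrb1 (4.39 ± 1.07), Rnf152 (3.60 ± 0.68) and Rnase2a (3.46 ± 0.71) rose. Asprv1 (-3.62 ± 0.34), Thbs1 (-2.71 ± 0.35) and the chemokine Cxcl5 (-4.10 ± 0.83) fell, with limma adjusted p up to 0.0382.

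Camera called 7 other lists for DKO against CDK19KO. Their adjusted p with an estimated correlation follows. Erythroid genes (all 29 lower, Car1 fell) had adjusted p = 0.528. Heme synthesis genes (all 13 lower) had adjusted p = 0.616. Megakaryocyte and platelet genes (all 23 lower, Thbs1 fell) had adjusted p = 0.528. Mature B cell genes (22 of 24 lower) had adjusted p = 0.785. Stromal, bone and vessel genes (22 of 28 lower) had adjusted p = 0.779. S phase genes (27 of 30 lower) had adjusted p = 0.697. Mitosis genes (25 of 30 lower) had adjusted p = 0.801. Erythroid and mature B cell genes were also lower in VAV against WT (28 of 29 and 23 of 24 members), so for them too Cdk8 deletion cannot be told apart from Cre or colony. With the erythroid level as a covariate the medians turned for heme synthesis (from -0.87 to 0.15) and stroma (from -0.37 to 0.03; -0.57 without CDK19KO replicate 1). The erythroid share of reads was 0.681 to 1.68% in CDK19KO, and CDK19KO replicate 4 and DKO replicate 4 carried the muscle transcripts. The count of 279 was 119 without CDK19KO replicate 2, 132 without CDK19KO replicate 3, 129 without CDK19KO replicate 4 and 124 without DKO replicate 2. It was 1251 with array weights, 968 with only these 2 groups in the fit, 601 with DESeq2, 97 without the 2 muscle-rich libraries, 880 without the 2 erythroid-rich libraries and 141 with the erythroid level as a covariate. Adgrb1 was not called without CDK19KO replicates 2 or 4 or DKO replicates 1, 2, 3 or 4 (adjusted p up to 0.142). Cxcl5 was not called without CDK19KO replicate 4 (adjusted p up to 0.0502). Rnase2a was not called without CDK19KO replicate 4 or DKO replicate 2 (adjusted p up to 0.0589). Ifit1 was not called without CDK19KO replicates 3 or 4 or DKO replicates 1 or 2 (adjusted p up to 0.0842). Cpa3 was not called without CDK19KO replicates 1 or 3 or DKO replicates 2 or 4 (adjusted p up to 0.0734). Prss34 was not called without CDK19KO replicates 1, 2 or 3 or DKO replicates 2 or 4 (adjusted p up to 0.0899). Cd8a was not called without DKO replicate 2 (adjusted p up to 0.0507). Car1 was not called without CDK19KO replicate 2 (adjusted p up to 0.0518). With 1 library left out the camera call was lost (adjusted p in brackets) for mature B cell genes without DKO replicates 1 or 2 (up to 0.288), stromal, bone and vessel genes without CDK19KO replicates 2 or 4 or DKO replicate 1 (up to 0.336) and mitosis genes without CDK19KO replicate 2 or DKO replicates 3 or 4 (up to 0.321).

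A set of 77 genes differed in DKO against VAV, CDK8KO and CDK19KO in the same direction, 45 higher and 32 lower. Of these, 60 (37 higher, 23 lower) also differed from WT, among them Perp, Upp1, Chit1, Fcer1a and Mcpt8 on the higher side and Asprv1, Cd163, Cd5l, Hmox1, Fcnb, H1f0, Nt5e, Thbs1 and Camp on the lower. The eosinophil genes Ear6, Prg3, Prg2 and Epx were not among the 60. The set of 77 was defined after the data were seen, and its comparisons share the DKO libraries, so they are not independent. Between DKO against VAV and DKO against CDK8KO, 75 higher and 51 lower calls were shared, where independent lists would share 1.22 and 0.632. Between DKO against VAV and DKO against CDK19KO the shared calls were 59 and 39, where independent lists would share 1.55 and 0.639. The number of 77 was 47 without DKO replicate 2, 50 without DKO replicate 3, 45 without DKO replicate 4, 51 without CDK19KO replicate 2, 20 with only the compared groups in each fit, 153 with DESeq2 and 33 without the 2 muscle-rich libraries.

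Few of the genes that changed in DKO were called in a single knockout, where few genes were called at all, so the overlaps below do not show that changes are unshared. No gene called in DKO against VAV was called in CDK8KO against VAV by limma (1 by DESeq2, 8 with WT as the control and 3 with the controls pooled), and Cdk19 alone was shared with CDK19KO against WT (3 genes by DESeq2; 0.0208 for independent lists of genes that fell). Over the 213 genes, 160 (75.1%) had the same sign in CDK8KO against VAV, with a median fold change 0.123 times that in DKO on the log2 scale, and 117 (54.9%) had the same sign in CDK19KO against WT, with a median of 0.0359 times. CDK8KO and DKO share the VAV libraries: over all genes Pearson's r was 0.348, against 0.504 in simulated groups with no effect, and the covariance 0.0645 against 0.0572. With the VAV libraries split between the comparisons, r was 0.000725, the covariance -0.00338 and the share of the same sign 68.2%. The correlation lay below the simulated value, genes are not independent replicates, and no shared effect is shown by these values.

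The interaction tests whether the effect of Cdk19 loss differs between the genotypes that carry Cdk8 deletion and Cre (CDK8KO, DKO) and those with neither (WT, CDK19KO). Cdk8 deletion cannot be told apart from Cre or colony in it. It passed for 21 genes, with a positive difference of log2 fold changes for 13 and a negative one for 8. The sign is not that of a change in DKO. Of the 13, 10 were also called higher in DKO against VAV, and of the 8 all 8 were called lower. Perp (difference of log2 fold changes 3.14 ± 0.47), Chit1 (3.30 ± 0.44) and Lipg, an endothelial lipase (3.39 ± 0.61), had positive differences, as did Acod1, which makes itaconate in activated macrophages (2.34 ± 0.46). Asprv1 (-3.91 ± 0.49), Cd163 (-2.38 ± 0.31), Fcnb (-2.37 ± 0.36) and H1f0 (-2.68 ± 0.30) had negative ones. Prox1 passed (2.64 ± 0.48) at levels of 2.82 ± 1.02 in CDK8KO and 19.03 ± 3.64 in DKO against 633 ± 186 in WT (SD). The histone gene H2bc24 passed (-7.52 ± 1.17), with 44.9 ± 12.3 in WT and 681 ± 277 in CDK19KO, but DKO replicate 1 held 481 and the other DKO libraries 11.6 to 36.0, and histone genes share sequence. The largest limma adjusted p of these 10 genes was 0.0446.

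Camera called 9 lists for the interaction, and none held with an estimated correlation. Higher, lower, rose and fell refer here to the sign of the difference of log2 fold changes. Eosinophil, basophil and mast cell genes (17 of 18 higher, 12 rose adjusted over the list alone) had adjusted p = 0.174 with an estimated correlation. T cell genes (all 23 higher, 4 rose adjusted over the list alone) had adjusted p = 0.57 with an estimated correlation. Interferon-stimulated genes (30 of 34 higher) had adjusted p = 0.57 with an estimated correlation. Monocyte and macrophage genes (Cd163 and Cd5l of 24 fell) had adjusted p = 0.57 with an estimated correlation. Erythroid genes (all 29 lower) had adjusted p = 0.57 with an estimated correlation. Heme synthesis genes (all 13 lower) had adjusted p = 0.57 with an estimated correlation. Megakaryocyte and platelet genes (20 of 23 lower) had adjusted p = 0.847 with an estimated correlation. S phase genes (29 of 30 lower) had adjusted p = 0.57 with an estimated correlation. Mitosis genes (29 of 30 lower) had adjusted p = 0.584 with an estimated correlation. With the erythroid level as a covariate the megakaryocyte and platelet median turned from -0.44 to 0.66 (camera adjusted p = 0.00502), and the heme synthesis median from -1.24 to 0.05. The median of the former was -0.19 without CDK8KO replicate 1, -0.74 without CDK19KO replicate 1 and -0.15 without CDK19KO replicate 2, and that of the latter -0.75 without CDK8KO replicate 1. The T cell level of DKO replicate 1 (6.69) was the lowest of the DKO libraries, with 7.83 to 8.12 in the others. The count of 21 was 10 without WT replicate 3 and 12 without CDK19KO replicate 2. It was 98 with DESeq2, 34 with array weights and 11 without the 2 muscle-rich libraries. Higher and lower genes numbered 10 and 12 with the covariate, and 8 and 9 without DKO replicate 3. Lipg was not called without WT replicates 1 or 3, CDK19KO replicates 2, 3 or 4 or DKO replicates 1, 2 or 3 (adjusted p up to 0.121). Prox1 was not called without WT replicates 1, 2 or 3, CDK19KO replicates 2, 3 or 4 or DKO replicates 1 or 4 (adjusted p up to 0.1). Acod1 was not called without WT replicates 1 or 3, CDK8KO replicates 1, 2, 3 or 4, CDK19KO replicates 2, 3 or 4 or DKO replicates 1, 2 or 3 (adjusted p up to 0.185). Cd5l was not called without WT replicates 1, 2 or 3, CDK8KO replicates 1, 3 or 4, CDK19KO replicates 1, 2, 3 or 4 or DKO replicates 1, 2 or 3 (adjusted p up to 0.172). With 1 library left out the camera call was lost (adjusted p in brackets) for monocyte and macrophage genes without CDK8KO replicate 4 (up to 0.0901) and megakaryocyte and platelet genes without WT replicates 1 or 3, CDK8KO replicate 1, CDK19KO replicate 2 or DKO replicates 1 or 3 (up to 0.523).

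The comparison of VAV with WT asks what the transgene itself changes, and 13 genes passed, 10 higher and 3 lower. Prox1 (ENSMUSG00000010175; chromosome 1, 190118035 to 190170714), a homeobox transcription factor, went from 633 ± 186 in WT (SD, n = 3) to 5.47 ± 2.01 in VAV (SD, n = 4), 98.9-fold lower (log2 fold change -6.63 ± 0.35, limma adjusted p = 2.0e-09). Commd10 rose (1.57 ± 0.20), as did the transglutaminase Tgm3 (1.52 ± 0.28), Klra17 (1.45 ± 0.22), the amino acid transporter Slc7a7 (1.21 ± 0.22) and the interferon-stimulated gene Cmpk2 (0.85 ± 0.15). Tmem267 (-1.36 ± 0.22) and the ribosomal protein gene Rpl5 (-0.83 ± 0.15) fell, with limma adjusted p up to 0.0392. Interferon-stimulated genes were higher for 33 of 34; Cmpk2 rose, and 11 rose adjusted over the list alone (camera adjusted p = 1.6e-09, and adjusted p = 0.677 with an estimated correlation). Cholesterol and lipid synthesis genes were higher for 24 of 27, with none past the test and 4 adjusted over the list alone, such as Srebf2 (1536 ± 75.6 in WT, 2550.4 ± 324 in VAV) (camera adjusted p = 2.8e-07, and adjusted p = 0.677 with an estimated correlation).

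No member passed in the 6 other lists called for VAV against WT. Early granulocyte genes (all 12 higher) had adjusted p = 0.909 with an estimated correlation. Late neutrophil genes (21 of 23 higher, 6 rose adjusted over the list alone) had adjusted p = 0.878 with an estimated correlation. Stress response genes (23 of 26 higher) had adjusted p = 0.677 with an estimated correlation. Mitosis genes (28 of 30 higher) had adjusted p = 0.909 with an estimated correlation. Erythroid genes (28 of 29 lower) had adjusted p = 0.909 with an estimated correlation. Mature B cell genes (23 of 24 lower) had adjusted p = 0.909 with an estimated correlation. The erythroid share of reads was 0.729 to 1.1996% in WT, 3.55% in VAV replicate 3 and 0.162 to 0.325% in the other VAV libraries. The count of 13 was 3 without WT replicate 1, 4 without WT replicate 2, 4 without WT replicate 3, 4 without VAV replicate 1, 4 without VAV replicate 2, 416 without VAV replicate 3 and 8 without VAV replicate 4. It was 640 with array weights, 320 with DESeq2, 3 with only these 2 groups in the fit, 7 without the 2 muscle-rich libraries, 1060 without the 2 erythroid-rich libraries and 43 with the erythroid level as a covariate. Prox1 and Commd10 were called with any 1 library left out. Tgm3 was not called without WT replicates 1, 2 or 3 or VAV replicates 1 or 2 (adjusted p up to 0.309). Klra17 was not called without WT replicates 1 or 2 or VAV replicate 2 (adjusted p up to 0.0696). Slc7a7 was not called without WT replicates 1, 2 or 3 or VAV replicates 1 or 4 (adjusted p up to 0.188). Cmpk2 was not called without WT replicates 1, 2 or 3 or VAV replicates 1 or 2 (adjusted p up to 0.196). Tmem267 was not called without WT replicates 1 or 3 or VAV replicates 1, 2 or 4 (adjusted p up to 0.196). Rpl5 was not called without WT replicates 1, 2 or 3 or VAV replicates 1, 2 or 4 (adjusted p up to 0.199). Leaving out 1 library lost the camera call (adjusted p in brackets) for early granulocyte genes without VAV replicate 4 (up to 0.153) and erythroid genes without VAV replicate 2 (up to 0.294).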

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

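The tests of muscle, of the erythroid share and of a larger share of eosinophils were chosen after the results were seen; the other tests in this part were set before. In groups of 4 libraries, a library was singled out when its gap to the nearest of the others took more of the group's range than Dixon's 95% limit for 4 values, and chance flags about 1 in 20 groups. Of 229 groups looked at 13 were found, with 11.45 expected by chance. For genes these were Pdzk1 in VAV replicate 3 (99.3 normalized counts, others 39.4 to 46.2), H1f0 in VAV replicate 4 (1199, others 751 to 828), Hspa1b in VAV replicate 1 (356, others 56.2 to 68.5), Prox1 in CDK8KO replicate 1 (4.35, others 2.19 to 2.50) and H2bc24 in DKO replicate 1 (481, others 11.6 to 36.0). VAV replicate 2 held 33.0 M reads, the others 25.5 to 26.5 M.

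The rest were mean log2 levels of gene lists. CDK8KO replicate 1 stood out for the megakaryocyte and platelet list (10.20, others 8.56 to 8.68), the S phase list (11.59, others 10.67 to 10.82) and the skeletal muscle list (4.51, others 2.24 to 2.49). CDK19KO replicate 1 stood out for B cell precursors (10.46, others 10.02 to 10.09), CDK19KO replicate 4 for muscle (10.74, others 2.61 to 2.64), DKO replicate 2 for interferon-stimulated genes (9.79, others 9.54 to 9.58) and VAV replicate 1 for mitosis (11.39, others 11.49 to 11.51).

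The effect of Cdk19 loss differed between the genotypes with Cdk8 deletion and Cre and those with neither, by the interaction test of limma, for 21 genes, given as the difference of log2 fold changes. Cdk8 deletion, Cre and colony cannot be told apart here. Positive differences were those of Dock9 (1.78), Spata13 (1.42), Chit1 (3.30), Perp (3.14), Clec4b2 (1.78), Reck (1.198), Il4ra (1.32), Prox1 (2.64), Lipg (3.39), Nav2 (1.52), Il17rb (1.92), Eml5 (1.26) and Acod1 (2.34). Negative differences were those of H1f0 (-2.68), Asprv1 (-3.91), Cd163 (-2.38), Fcnb (-2.37), H2bc24 (-7.52), Vnn3 (-2.31), Cd5l (-1.87) and Nt5e (-2.09). In 2 of 100 random assignments of the libraries to groups, the real one included, as many genes passed, and the highest other count was 48, so a chance split is an unlikely but not excluded source of the count.

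For DKO against VAV, 1 of 35 splits of the libraries called as many genes as the real 213, which was the real split itself, and the highest other split called 3 genes. Without the 2 muscle-rich libraries 96 of the 213 were still called and all 213 kept their sign. The median ratio of their log2 fold changes to those with all libraries was 0.986 (quartiles 0.927 to 1.03). The 213 were picked with all libraries and both fits share the remaining ones, so a ratio near 1 was partly built in. Why calls were lost was not tested. With the erythroid level as a covariate the ratio was 0.997 and 213 were called. Of the called genes 5.63% lay within 20 Mb of Cdk8, Cdk19 or Commd10, against 4.22% of the tested genes (Fisher's exact p = 0.30), so DNA linked to these loci cannot account for most of them. An effect of losing both kinases remains open and so does an effect of Cdk19 loss that depends on Cre or colony and not on Cdk8, since the Cdk8 genotype rests on the labels. A difference between litters or housing was not testable.

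For the other comparisons the same test of splits gave 1 of 35 for DKO against CDK8KO (highest other split 8 genes), 1 of 35 for DKO against CDK19KO (highest other 1) and 1 of 35 for CDK19KO against WT (highest other 1). For CDK8KO against VAV the test says nothing, since with a real count of 0 all 35 of 35 splits reach it by construction. The split that set VAV replicate 3 and CDK8KO replicates 1, 2 and 3 against the rest called 2079 genes, and it also parted the libraries by the mean log2 level of the erythroid list (11.17 to 13.43 against 9.25 to 10.37). For VAV against WT 2 of 35 splits (5.71%) called as many as the real 13, and WT with VAV replicate 3 against VAV replicates 1, 2 and 4 called 684, so chance cannot be excluded there. That split parted the erythroid levels too (11.15 to 12.75 against 9.25 to 10.20).

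The higher eosinophil, basophil and mast cell genes in DKO were weighed against 3 explanations. No single DKO library was the source of the list's median, since the lowest median log2 fold change without any 1 of them was 1.02, against 1.14 with all. Leaving out 1 library cannot tell whether 2 carried most of the rise. The mean log2 level of the list was 10.23 and 9.80 in DKO replicates 3 and 4, and 9.06 and 9.03 in replicates 1 and 2. All of these lay above the 7.88 to 8.63 of VAV. Reads shared between Ear paralogs are excluded as the whole source, since the 15 other members had a median of 1.09. Whether eosinophils were more numerous or expressed more of these genes cannot be told: the surface receptors Il5ra, Siglecf and Ccr3 had a median of 1.09 and the granule protein genes 2.51, and cell counts were not analysed here.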

How the results depend on the processing

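The settings without muscle-rich or erythroid-rich libraries and with the erythroid covariate, the list counts with TMM and quantile scaling, and the settings of the overlaps and of the genes shared by the DKO comparisons were chosen after the data were seen. Of the alternatives for named genes 2335 kept direction and side of the threshold, 349 kept the direction only and 7 reversed; for gene lists these numbers were 1020, 305 and 16. Where a count moved, the cause was not tested, other than that settings with fewer libraries or groups leave fewer degrees of freedom. With only the compared groups in the fit, the genes changed numbered 1 for CDK8KO against VAV, 99 for DKO against VAV, 3 for VAV against WT, 31 for DKO against CDK8KO and 968 for DKO against CDK19KO, and the genes shared by the DKO comparisons 20. With DESeq2 they numbered 1 for CDK8KO against VAV, 15 for CDK19KO against WT, 504 for DKO against VAV, 320 for VAV against WT, 711 for DKO against CDK8KO, 601 for DKO against CDK19KO and 98 for the interaction, the shared genes 153, and the overlaps of DKO with CDK8KO 1 and with CDK19KO 3. With array weights there were 7 for CDK19KO against WT, 640 for VAV against WT, 106 for DKO against CDK8KO, 1251 for DKO against CDK19KO and 34 for the interaction. Without a filter CDK19KO against WT gave 6. Without the muscle-rich libraries there were 1 for CDK19KO against WT, 102 for DKO against VAV, 7 for VAV against WT, 92 for DKO against CDK8KO, 97 for DKO against CDK19KO and 11 for the interaction, and 33 shared genes. Without the erythroid-rich libraries there were 385 for DKO against VAV, 1060 for VAV against WT and 880 for DKO against CDK19KO. With the erythroid covariate there were 606 for DKO against VAV, 43 for VAV against WT and 141 for DKO against CDK19KO. With WT as the control CDK8KO gave 12 genes (overlap with DKO 8), with pooled controls 4 (overlap 3) and DKO 366, and with VAV as the control CDK19KO gave 12.

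With an estimated correlation camera called 0 lists for 6 of the comparisons and 1 for DKO against CDK8KO. By fry the numbers were 0 for CDK8KO against VAV, CDK19KO against WT, VAV against WT and the interaction, 2 for DKO against VAV, 4 for DKO against CDK8KO and 5 for DKO against CDK19KO. With the erythroid covariate 4 lists were called for CDK8KO against VAV and 7 for DKO against CDK19KO, and with quantile normalization 6 for CDK19KO against WT. Median log2 fold changes of lists turned with the covariate for heme synthesis in CDK8KO against VAV (-0.0535), DKO against CDK8KO (0.0545), DKO against CDK19KO (0.151) and the interaction (0.0458). They also turned for erythroid genes in DKO against VAV (0.0114), VAV against WT (0.0152), DKO against CDK19KO (0.0170) and the interaction (0.0248), where the covariate is the list itself. Megakaryocyte genes turned to 0.40 in DKO against CDK8KO (camera adjusted p = 0.0128) and 0.66 in the interaction (camera adjusted p = 0.00502), and stroma to 0.0275 in DKO against CDK19KO. Without the erythroid-rich libraries, and without VAV replicate 3 alone, erythroid genes in DKO against VAV turned to 0.26 (range with 1 library left out -0.93 to 0.26). Without CDK8KO replicate 1 the S phase list in CDK8KO against VAV turned to -0.0265 (range -0.0265 to 0.31). Without CDK8KO replicate 3 the mature B cell list turned to -0.13 there (range -0.13 to 0.53) and to 0.0333 in DKO against CDK8KO (range -0.57 to 0.0333). Cdk8 in CDK8KO turned to -0.33 against WT, -0.15 against pooled controls and -0.20 with the covariate, and to -0.08, -0.03, -0.11 and -0.01 without VAV replicates 2 or 4 or CDK8KO replicates 1 or 2.

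With each library left out in turn the genes changed ranged over 0 to 1 for CDK8KO against VAV, 1 to 2 for CDK19KO against WT, 107 to 226 for DKO against VAV, 3 to 416 for VAV against WT, 105 to 422 for DKO against CDK8KO, 119 to 227 for DKO against CDK19KO, 10 to 21 for the interaction and 45 to 77 for the genes shared by the DKO comparisons. Lists called ranged over 7 to 13 for CDK8KO against VAV, 2 to 9 for CDK19KO against WT, 12 to 16 for DKO against VAV, 7 to 13 for VAV against WT, 14 to 17 for DKO against CDK8KO, 10 to 14 for DKO against CDK19KO, 8 to 12 for the interaction. The overlap with DKO stayed at 0 for CDK8KO, where at most 1 gene was called, and at 1 for CDK19KO, which was Cdk19 itself. With so few calls these overlaps do not measure how far changes are shared. The log2 fold change of Cdk19 ran from -1.57 to -1.50 in CDK19KO and -1.72 to -1.55 in DKO, and that of Cdk8 from -0.11 to 0.19 in CDK8KO and -0.39 to -0.15 in DKO.

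With a replicate block the genes changed were 0, 1, 196, 18, 204, 263 and 14 in the order of the ranges above, and the lists 12, 6, 14, 11, 17, 13 and 12; it moved only CDK19KO against WT by over 1.5 times (1 gene, 6 lists). The numbers do not pair the libraries: 6 of 36 same-number pairs had r over 0.1 (range -0.274 to 0.306), the median r was 0.00827 against 0.00189 for other pairs, and 4 of 19 libraries correlated best with their own number. A sex covariate was not run, since all 19 libraries express Y-linked genes. TMM and quantile scaling shifted the median log2 fold change of a comparison by values from -0.0185 to 0.0162. Depth, from 14881701 to 33010241 reads, limits what can be said of genes under the filter.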

Other observations

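The genes in this part were chosen after their values were seen. The 12 libraries whose labels carry Cre differed from the 7 others in 275 genes by limma, 193 higher and 82 lower. Of these, 12 changed by over 2-fold with no overlap between the libraries. Prox1 held 2.19 to 22.5 normalized counts in the Cre libraries and 332 to 941 in the others. Sva, a seminal vesicle gene, had 20.4 to 42.1 in every Cre library and 0 in every other, at least 5.12-fold higher in each Cre library at the floor of 3 reads per library. The others were Commd10 (1055 to 2150.4 with Cre, 328 to 502 without), Chil5 (143 to 564 with Cre, 66.5 to 141 without), Klra17 (182 to 402 with Cre, 89.1 to 150.4 without), Rasgrf2 (102 to 286 with Cre, 28.1 to 80.5 without), Me3 (3717 to 13407 with Cre, 2350.1 to 3666 without), Srgap1 (35.7 to 214 with Cre, 20.7 to 32.8 without), Ucp3 (3.32 to 14.1 with Cre, 20.6 to 41.2 without), Zfp987 (54.9 to 143 with Cre, 25.6 to 52.4 without), Ston1 (10.2 to 64.4 with Cre, 67.7 to 130.3 without) and Igkv12-89 (0 to 32.2 with Cre, 40.3 to 101 without). DKO had the highest mean of Chil5 and of Srgap1: the means for WT, VAV, CDK8KO, CDK19KO and DKO were 98.98, 165, 183, 128 and 474 for Chil5 and 26.1, 44.8, 68.4, 25.6 and 146 for Srgap1.

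Such genes could come from DNA carried along with the transgene's insertion. This was tested by position: 8.33% of the 12 genes, which is Commd10 alone, lay within 20 Mb of it, so DNA linked to that site does not account for the set. A difference in red cell content is not the source either, since 100% of the 12 were called with the erythroid level as a covariate. Among all tested genes 26 separated the groups with no overlap, where 0.555 would be expected by chance. An effect of Cre, other DNA from the transgene's founder and a difference between colonies remain open, because Cre and colony cannot be told apart in these libraries. For DKO against CDK19KO, whose libraries differ in Cre, Prox1 and Commd10 are therefore not evidence on Cdk8, nor is Prox1 in the interaction. The same holds in DKO against CDK19KO for the lists that camera called in the same direction in VAV against WT: interferon-stimulated and cholesterol and lipid synthesis genes (higher), and erythroid and mature B cell genes (lower).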
